A study of Drosophila melanogaster with 2 samples.

How the data were processed

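Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map the DNA bound by CG10147, a predicted zinc finger protein of Drosophila melanogaster. Per the labels, the flies carried a transgene with GFP joined to the carboxyl end of CG10147, whole mixed-sex embryos aged 0 to 24 hours were collected, the chromatin was sonicated to fragments of 200 to 800 bp, and an antibody against GFP was used for the precipitation. The series as analysed here held 1 group with 2 libraries, named in the labels as biological replicates 2 and 3. No second condition was part of the design, so the comparisons were between the replicates, and between peak positions and the annotated genome.

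The authors deposited 4 peak lists. Per the labels' file lists, a list was called on each replicate with a control, and another on both alignments pooled with a control. A final list was thresholded by a measure of reproducibility between replicates (irreproducible discovery rate, IDR). The assembly was dm6, per the same lists. The peak caller, the aligner and the read filters were not given in the sources used here, and the control was not analysed here. Each peak carried a signal value from the authors' peak caller, whose unit beyond that was not given, and a significance that the authors deposited as −log10 of a q-value. Signal values were used to rank, describe and filter peaks within a list, and were not compared between lists except by correlation. Read depth was not part of the peak lists, so the depth behind each value is unknown and no interval for a single peak's signal was made.

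The replicate lists and the pooled list each held exactly 30000 peaks; whether the lists were capped at that number was not given in the sources used here. The −log10 q values stopped at a single maximum in each list, 4.13 in the pooled list, where 6710 peaks sat at it, so signal and not significance was used for ranking. The IDR list held 4576 peaks, and its rows were the 4576 strongest rows of the pooled list. It is therefore a cut by signal of a list made from both libraries together, and no stronger pooled peak was left out. A place in it does not show that a peak was found in each replicate. Of its peaks, 4117 (90.0%) had a summit within 100 bp in both replicate lists, and 2820 (61.6%) in the strongest 4576 of both. The replicates were compared through their own lists. In the IDR list, 21 regions appeared again with another summit, and 1 summit lay past the end of its region. All were kept.

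Genes came from the Ensembl release 115 copy of FlyBase annotation 6.54, and sequence from the Release 6 assembly, which shares its coordinates with dm6. Every peak ended within the length of its chromosome arm. Annotated transposable elements were left out. A promoter was the sequence within 500 bp of any annotated transcription start site (TSS). Each summit was given the first class that applied among promoter, 5' UTR, 3' UTR, coding sequence (CDS), other exon, intron and intergenic, and the same rule was applied to every base of arms 2L, 2R, 3L, 3R, 4 and X. A gene had a promoter peak when a summit lay within 500 bp of one of its TSSs.

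Replicate agreement was the share of the 4576 strongest peaks of a replicate with a summit of the other replicate's 4576 strongest within 100 bp. It was set against 1000 circular shifts of positions within each arm, one-sided. Signal correlation was computed across IDR peaks matched to a summit in both replicate lists. Shares of peaks were tested with two-sided exact binomial tests and given with exact Clopper-Pearson 95% intervals, which cover counting error only. Gene lists were tested with Fisher's exact test against all other protein-coding genes, or all other genes for tRNA and snRNA lists, with Benjamini-Hochberg adjustment over 25 lists. An alternative drew each list 10000 times within 5 bins of TSS number, a permutation of list membership. Neighbouring genes can share a peak, so genes are not fully independent in these tests. Medians were compared with permutation tests of 100000 resamples, whose smallest p is 1e-05. Motifs from a list of 20 consensus sequences, and all 7-mers, were counted in 200 bp windows around summits and in windows 1000 bp away on a random side, and compared with exact McNemar tests, adjusted over all motifs or k-mers. A p from peaks describes positions in these pooled libraries, not variation between embryos.

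Gene lists, motifs, tests and the rule for named genes were chosen before the data were examined. The rule named the 25 IDR peaks with the highest signal, CG10147, up to 4 members of each list with the strongest promoter peaks, and the 10 motifs or k-mers with the lowest adjusted p. Ribosomal and similar lists were made from symbols. Zinc finger lists were made from protein patterns, with at least 3 C2H2 matches, and a ZAD-like list had in addition a pattern of paired cysteines near the start of the protein. Older symbols of 8 genes were matched to their current names. The alternatives tried were other TSS windows, other summit distances, stricter lists, each replicate alone, summits outside soft-masked repeats, peaks merged within 1000 bp, other backgrounds and other window sizes. Control windows matched on GC content and annotation class, the restriction to peaks found in both replicates' strongest 4576, shares of arms without Y, and the rank of the CG10147 peak in each replicate were added after the data had been seen.

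The tests were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. They were first tested on simulated data. Of 200 simulated lists of 80 genes among 14000 with odds raised 5 times, 100% were called with a median odds ratio of 4.94, and 6.5% of lists with no effect were called. A 7-mer planted in 20% of 2000 windows ranked first of 8192, with 0 calls without planting. Both sides of this simulation had the same base composition, unlike summits and flanks in the data. It therefore does not show how many calls a difference in GC content alone would give. The permutation test called 98% of 50 pairs of groups shifted by 0.5 SD and 4% of 50 unshifted pairs.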

Results

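DNA bound by CG10147-GFP was mapped by ChIP-seq in whole Drosophila embryos aged 0 to 24 hours, in 2 biological replicates. CG10147 (FBgn0035702) lies on 3L from 6486167 to 6488424 on the minus strand of dm6, and its longest protein has 448 residues, 9 matches to the C2H2 zinc finger pattern and a ZAD-like start. The deposited lists held 30000 peaks for each replicate and for the pooled libraries, and 4576 peaks in the list thresholded by reproducibility (IDR peaks). IDR peaks had a median signal of 228.7 in the authors' peak caller units and a range from 144.6 to 4880. The median region was 384 bp wide. Coordinates are 1-based on dm6, and signal values are the authors' own and carry no replicate error.

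The first question was how far the replicates shared their binding sites. Of the 4576 strongest peaks of replicate 3, 2817 (61.6%) had a summit within 100 bp among the 4576 strongest of replicate 2. Shifted positions gave 0.692% on average and at most 1.11% (permutation by 1000 circular shifts, one-sided p = 0.001, the smallest they can give). Across the 4117 IDR peaks matched in both replicate lists, the signals correlated with a Spearman rho of 0.635 (bootstrap 95% interval 0.616 to 0.658) and a Pearson r of 0.723 on the log2 scale. This is across peaks, which are not independent replicates. Among the strongest 1144 peaks rho was 0.657, and in the next sets of 1144, which like the list itself were cut by pooled signal, it was -0.255, -0.607 and -0.651. Cutting to a narrow range of pooled signal can by itself make these values negative, because both replicates make up that signal. These correlations therefore do not measure agreement at weaker peaks. Of the strongest 1144 IDR peaks, 97.6% had a summit within 100 bp in the strongest 4576 of both replicates. The share fell to 83.1%, 53.8% and 11.9% (136 of 1144) in the next sets. Weak peaks lie near the cut of these lists, which can lower their share. In the full replicate lists, 1121 of the strongest 1144 and 942 of the weakest 1144 had a summit in both.

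**Figure D1:**
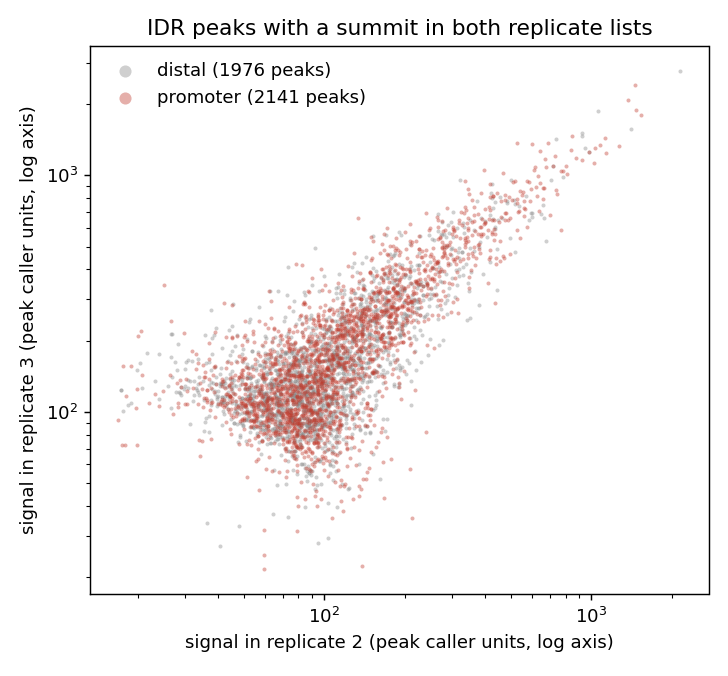
Signal of IDR peaks in replicate 2 (x axis) and replicate 3 (y axis), both in peak caller units on log axes, with a point for each of the 4117 peaks with a summit within 100 bp in both lists, red for promoter and grey for distal peaks. The strongest peaks lie along a line, and the cloud widens towards low signal (Spearman rho 0.635).

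The strongest binding lay in introns and promoters of genes with varied roles. The top peak (2L, 6612308 to 6613071, signal 4880) was in an intron of CG11050, 1022 bp from its nearest TSS, and ranked 1 in replicate 3 and 12 in replicate 2, where only mitochondrial peaks ranked above it. The next was at the promoter of lncRNA:CR44619 within lncRNA:Vinr (X, 12750831 to 12751683, signal 3900), followed by the promoters of mRpL41, a mitochondrial ribosomal protein gene (2R, 15217572 to 15217934, signal 3338), CG14100 (3L, 19590402 to 19590829, signal 3258) and Ugalt, a UDP-galactose transporter gene (X, 2703692 to 2704105, signal 3231). Introns of genes for transcriptional regulators were also among the 25 strongest: ush, a cofactor of GATA factors (2L, 480869 to 481297, signal 2934), and Trl, which encodes the GAGA factor (3L, 14759288 to 14759828, signal 2857). The TSS nearest to the ush site was that of another gene, cbt, 1426 bp away. A further peak lay in intronic sequence within the annotated spans of both HmgD and HmgZ, genes of HMG-box chromatin proteins (2R, 21703110 to 21703669, signal 2367).

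Promoters in the rest of the 25 were those of px (signal 2594), Art3 with mRpS10 (2536), SLC5A11 with lncRNA:CR44120 (2350), Gapdh2 (2346), CG18549 (2340), CG18428 with eIF4EHP (2227), CG11309 with CG7632 (2114), PNPase (2095), the Polycomb group gene ph-p (2078), CG1635 (2015), CG9147 with Fbw5 (2007), Pdrg1 with Pal1 (2000) and CG31145 (1966). Introns of Lk6 (signal 2258) and CG32772 (2206), and intergenic sites nearest to DNAlig3 (2287) and lncRNA:CR45695 (2130), completed the set. The lowest rank that any of these 25 peaks took was 71 in replicate 2 and 29 in replicate 3.

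A peak lay at the promoter of CG10147 itself. With its summit 182 bp upstream of the CG10147 TSS (3L, 6488399 to 6488762), it had a signal of 1540 and ranked 44 of 4576 IDR peaks. The same site ranked 64 of 30000 in replicate 2 (signal 639.4) and 51 of 30000 in replicate 3 (signal 928.6). The summit also lay 75 bp upstream of the TSS of Bulli, the divergent neighbour, so the peak belongs to a shared promoter region. No other peak of any list had its summit within 2000 bp of CG10147.

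Binding was concentrated at promoters. Of 4576 IDR summits, 2424 lay within 500 bp of a TSS (53.0%, 95% interval 51.5 to 54.4), against 13.6% of bases, a 3.90-fold excess for which the exact binomial p was computed as 0. Weaker pooled peaks with no IDR peak nearby were at promoters less often, 6027 of 24286 (24.8%; Fisher's exact test, odds ratio 3.41, 95% interval 3.20 to 3.64, p = 1.34e-297). Summits sat mainly on the upstream side, 1857 upstream against 559 downstream of the nearest TSS (76.9%, exact binomial test against equal sides, p = 1.07e-161). Their median position was 103 bp upstream (-103 bp). The sides were not weighted by their share of promoter bases, and a summit between divergent TSSs counts as upstream.

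Coding sequence was nearly free of summits, with 6 of 4576 (0.131%) against 13.1% of bases (adjusted exact binomial p = 3.41e-265). Depletion was also seen in 3' UTRs (35 summits, 0.765% against 5.07%, adjusted exact p = 4.79e-60), intergenic sequence (525, 11.5% against 27.1%, adjusted exact p = 6.59e-148), introns (1531, 33.5% against 39.5%, adjusted exact p = 4.17e-17) and 5' UTRs outside the promoter window (20, 0.437% against 0.780%, adjusted exact p = 0.00804). The 5' UTR call was lost with replicate 2 alone (adjusted exact p = 0.128), among peaks in both replicates (adjusted exact p = 0.0623) and with a TSS window of 200 bp (adjusted exact p = 0.546), where the intron call was lost too (adjusted exact p = 0.0911). Other exons held 35 summits (0.765% against 0.821%, adjusted exact p = 0.743), not a detectable difference. Intronic summits had a median distance of 2622 bp to a TSS, and 42.8% of them were within 2000 bp of one.

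**Figure D2:**
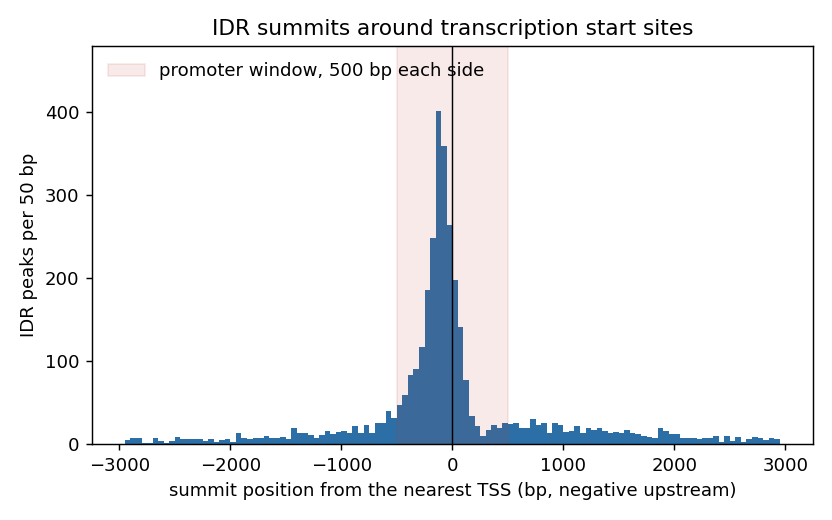
Number of IDR summits (y axis) per 50 bp of distance to the nearest TSS (x axis, bp, negative upstream), with the promoter window shaded and summits beyond 2950 bp not drawn. The peak of the distribution lies upstream of the TSS, with a median of -103 bp among the 2424 promoter summits.

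Promoter peaks were slightly stronger than distal ones, with a median signal of 239.7 (quartiles 179.3 and 388.7) for 2424 promoter peaks and 219.8 (quartiles 174.3 and 318.4) for 2152 distal peaks (difference 19.95, permutation test, p = 2e-05). With replicate 2 alone the difference, in that list's own signal, was 3.17 (permutation test, p = 0.0612), and with a promoter window of 200 bp it turned to -4.18 (permutation test, p = 0.316).

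Binding was spread over the large chromosome arms and sparse on chromosome 4. The density was 35.4 peaks per Mb on 2L, 32.6 on 2R, 36.1 on 3L, 33.6 on 3R and 34.7 on X, and 12.02 on 4, where 16 peaks were found (adjusted exact binomial p = 5.80e-06). Arm 3L exceeded its share of sequence when Y was counted in the total (22.1% of peaks against 20.4%, adjusted exact p = 0.0131). This call was lost without Y (against 20.9%, adjusted exact p = 0.169), with replicate 2 alone (adjusted exact p = 0.270), among peaks found in both replicates (adjusted exact p = 0.310), among the stronger 2288 peaks (adjusted exact p = 0.244) and outside repeats (adjusted exact p = 0.377). Among promoter peaks, chromosome 4 held 9 (0.371% against 0.793% of promoter sequence, adjusted exact binomial p = 0.0544), and no large arm departed from its share of promoters. No list held a peak on Y, and whether Y was kept in the authors' processing was not given in the sources used here.

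Genes of protein synthesis and turnover carried promoter peaks more often than other genes. Of 13945 protein-coding genes, 2836 (20.3%) had one. Of 86 cytoplasmic ribosomal protein genes, 61 (70.9%) did (Fisher's exact test, odds ratio 9.75, 95% interval 6.11 to 15.6, adjusted exact p = 1.23e-22), including RpS27 (signal 850.9), RpL34b (774.0) and RpL34a (652.4). Mitochondrial ribosomal protein genes had 27 of 73 (37.0%, odds ratio 2.31, adjusted exact p = 0.00388), including mRpL41 (3338), mRpS10 (2536), mRpS23 (1657) and mRpL23 (1124). This call was lost among peaks in both replicates (adjusted exact p = 0.151). Translation factors had 19 of 51 (37.3%, odds ratio 2.33, adjusted exact p = 0.0133), with eIF4EHP (2227), eIF6 (1161), eEF1gamma (693.2) and eIF3c (406.7) the strongest. This call was lost among the stronger 2288 peaks (adjusted exact p = 0.327). Subunits of the proteasome, a protein-degrading complex, had 14 of 32 (43.8%, odds ratio 3.06, adjusted exact p = 0.00926). Rpn5 (386.6), Rpn13 (339.9), Prosbeta2 (338.7, with no summit within 100 bp in the replicate 2 list) and Rpn11 (335.4) led the list. Its call was lost with replicate 2 alone (adjusted exact p = 0.0747), among peaks in both replicates (adjusted exact p = 0.140) and among the stronger 2288 peaks (adjusted exact p = 0.392). The excess was uneven over subunits. Grouped by symbol after the peaks had been seen, Rpn genes had 8 of 14, Prosalpha genes 3 of 12 and Prosbeta genes 2 of 13.

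Glycolytic and chromatin architecture genes were the other enriched groups. Of 12 glycolysis genes, 8 had a promoter peak (66.7%, odds ratio 7.85, 95% interval 2.36 to 26.1, adjusted exact p = 0.00271): Gapdh2 (signal 2346), Eno, which encodes enolase (1827), Hex-A, a hexokinase gene (1495), and Ldh, the lactate dehydrogenase gene (1018), were the strongest. When genes were matched on their number of TSSs, 8 against an expected 4.28 no longer passed the test (adjusted permutation p = 0.137). Architectural and insulator protein genes had 10 of 16 (62.5%, odds ratio 6.55, 95% interval 2.38 to 18.0, adjusted exact p = 0.00142), with Chro, the chromator gene (1809), Cp190 (1241), M1BP (540.0) and Dref (417.7) the strongest.

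Lists of regulators of embryonic pattern and of tissue identity did not pass the test. Hox genes had 0 of 8 (adjusted exact p = 0.490), segmentation genes 1 of 25, hry at a signal of 177.5 (adjusted exact p = 0.0893, and 0.0428 with a TSS window of 1000 bp, odds ratio 0.137), neural genes 4 of 25 (adjusted exact p = 0.804), mesoderm and muscle regulators 3 of 19 (adjusted exact p = 0.804) and muscle structural genes 3 of 20 (adjusted exact p = 0.804). Single members were nevertheless bound, such as elav, a neuronal RNA-binding protein gene (signal 1417), tin, a regulator of heart formation (397.7), and sls, which encodes a giant muscle protein (288.0). The Polycomb group had 3 of 20 (adjusted exact p = 0.804), namely ph-p (2078), E(z) (560.4) and Su(z)12 (319.9). The Su(z)12 peak had no summit within 100 bp in the replicate 3 list, and the hry peak had none in the replicate 2 list. Notch pathway genes had 10 of 27 (adjusted exact p = 0.0904), led by E(spl)m3-HLH (767.6) and neur (639.4), and passed the test with replicate 3 alone (odds ratio 2.66, adjusted exact p = 0.0351).

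Oxidative phosphorylation genes had 24 of 84 (28.6%, adjusted exact p = 0.118), led by ND-ASHI (915.6). They passed the test with a TSS window of 200 bp (odds ratio 2.07, adjusted exact p = 0.0128). Cell cycle and replication genes had 11 of 39 (adjusted exact p = 0.341), led by Dp (482.7). Heat shock and chaperone genes had 7 of 26 (adjusted exact p = 0.577), led by Hsp27 (873.9). They passed the test with replicate 2 alone (odds ratio 2.82 against 1.44, adjusted exact p = 0.0417). RNA polymerase II subunits had 4 of 12 (adjusted exact p = 0.388), led by Polr2B (521.7), and germline genes 5 of 20 (adjusted exact p = 0.691), led by orb (697.9). Genes of C2H2 zinc finger proteins, the family of CG10147, had 60 of 232 (25.9%, odds ratio 1.37, adjusted exact p = 0.0893), with Cp190, CG1602 (1184) and cbt (987.5) the strongest after CG10147 itself. The ZAD-like members had 26 of 89 (29.2%, odds ratio 1.62, adjusted exact p = 0.0893), including CG1792 (956.0), CG18476 (828.8) and CG4820 (559.5); with genes matched on their number of TSSs this list passed the test (26 against an expected 15.02, adjusted permutation p = 0.0164).

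Several groups had few promoter peaks or none. Chemoreceptor genes had 0 of 179 (adjusted exact p = 3.43e-17), replication-dependent histone genes 0 of 111 (adjusted exact p = 1.28e-10) and chorion and yolk genes 0 of 16 (adjusted exact p = 0.0920). The histone genes lie in a repeated array and also had no peak in the pooled list of 30000, so reads that map to several copies limit what can be said of them. Of 295 tRNA genes, 27 had a peak (9.15% against 17.2% of other genes, odds ratio 0.486, adjusted exact p = 0.000765), led by tRNA:Tyr-GTA-1-8 (1118). This call was lost with replicate 2 alone (adjusted exact p = 0.175) and with genes matched on TSS number (adjusted permutation p = 0.153). The snRNA genes had 1 of 32 (odds ratio 0.157, adjusted exact p = 0.0816), snRNA:7SKa. Their odds ratio was 0.872 with replicate 2 alone (adjusted exact p = 1), and it was 0 and passed the test with replicate 3 alone (adjusted exact p = 0.0108) and with peaks merged within 1000 bp (adjusted exact p = 0.0166). With only genes that had a pooled peak at a TSS as background, the cytoplasmic ribosomal protein and tRNA lists alone passed the test. Without summits in soft-masked repeats, the mitochondrial ribosomal, proteasome, glycolysis and tRNA lists no longer passed it.

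**Figure D3:**
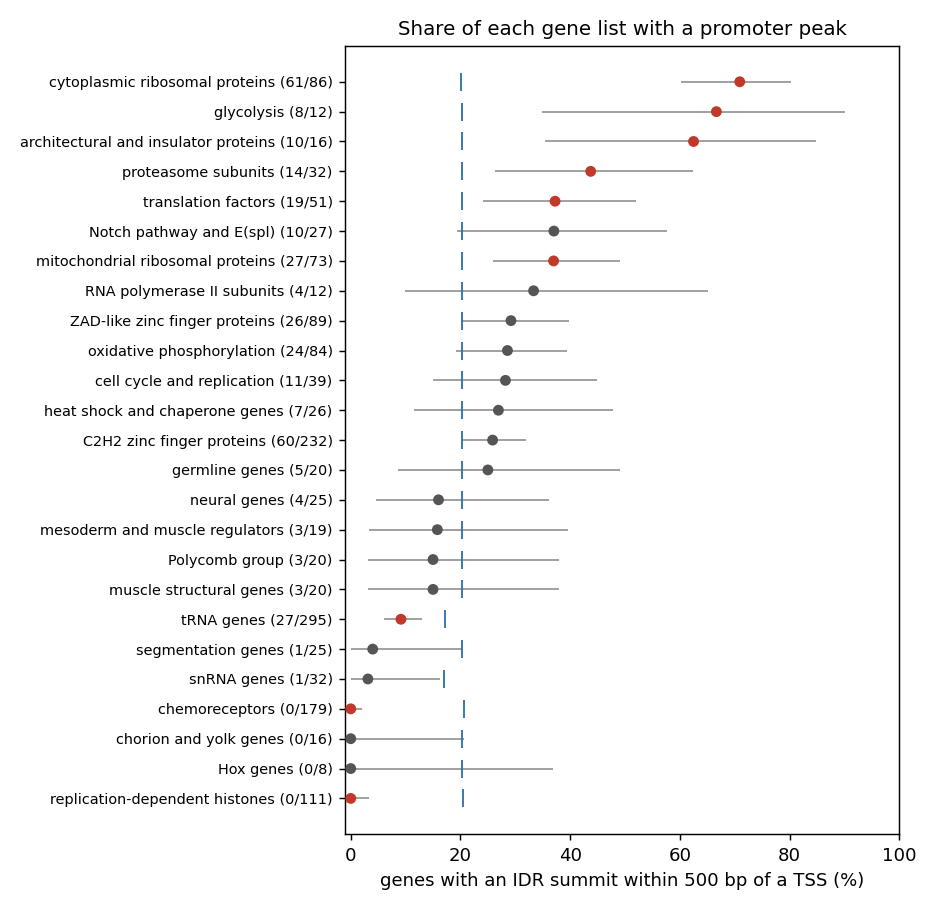
Share of genes in each of 25 lists with an IDR summit within 500 bp of a TSS (x axis, percent), with exact 95% intervals as lines, red points for lists with an adjusted p below 0.05 and blue ticks for all other genes. Cytoplasmic ribosomal proteins (70.9%) lie highest, and the histone, Hox, chorion and chemoreceptor lists lie at 0.

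Divergent promoters were bound more often than others. Of 4134 protein-coding genes with an opposite-strand TSS of another gene within 500 bp upstream, 1517 (36.7%) had a promoter peak, against 1319 of 9811 others (13.4%; Fisher's exact test, odds ratio 3.73, 95% interval 3.43 to 4.07, p = 8.45e-199). A divergent promoter has more TSSs near it, and both of its genes can be counted for a single peak.

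IDR summits were rich in A and T. The GC content of 200 bp summit windows was 34.7% ± 7.45 (SD, n = 4576), against 42.5% ± 9.55 in flanks 1000 bp away, and it was lower than in other promoter windows at promoters (35.5% ± 8.01 against 42.6% ± 9.48) and than in other introns in introns (33.7% ± 6.42 against 40.2% ± 7.86). Within the pooled list, GC rose from 31.9% for ranks 1 to 500 to 41.4% for ranks 15001 to 30000, while the promoter share fell from 66.8% to 19.9%. The most enriched 7-mers had no G or C: AAAATAT was in 29.5% of summit windows and 13.4% of flanks (adjusted exact McNemar p = 2.10e-74), TTTAAAA in 25.04% and 10.7% (adjusted exact p = 2.52e-69), and TAAAATA in 23.4% and 9.55% (adjusted exact p = 1.10e-67). Of 8192 7-mers, 1150 were more and 2608 less frequent at summits. Peaks with AAAATAT had a median signal of 243.6 (1348 peaks) against 222.5 (3228 peaks; permutation test, p = 1e-05, the smallest it can give). Among the stronger 2288 peaks this difference was 14.4 (permutation test, p = 0.141).

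Known promoter motifs were also more frequent at summits than in flanks. TATCGATA, the site of Dref, was in 188 summit windows (4.11%) and 25 flanks (0.546%; adjusted exact McNemar p = 8.44e-31). The TATA box was in 16.0% against 8.54% (adjusted exact p = 9.69e-26), the homeobox-type sequence TAATTA in 19.3% against 11.9% (adjusted exact p = 1.81e-21), Ohler motif 7 in 5.27% against 2.19% (adjusted exact p = 1.82e-14), the BEAF-32 core CGATA in 29.3% against 22.3% (adjusted exact p = 5.50e-14), and the M1BP site GGTCACACT in 1.70% against 0.393% (adjusted exact p = 9.02e-10). Of the 20 motifs, 8 were higher and 8 lower at summits. The lower ones included the core sequence of CTCF (5.53% against 7.95%, adjusted exact p = 8.99e-06) and the GAGA site (19.7% against 22.2%, adjusted exact p = 0.00503); both turned higher at summits with control windows matched on GC content and class. With those matched controls the Dref site stayed 3.24 times as frequent at summits (adjusted exact p = 1.75e-16) and Ohler motif 7 3.44 times (adjusted exact p = 3.73e-22), while the TATA box (15.4% in controls, adjusted exact p = 0.495) and TAATTA (18.2%, adjusted exact p = 0.272) no longer passed the test. Peaks with the Dref site had a lower median signal than the rest, 194.1 against 230.0 (adjusted permutation p = 0.0065). Against promoters without a peak, the Dref site was in 7.38% of promoter peaks and 6.69% of promoters (adjusted Fisher's exact p = 0.353), the BEAF-32 core had a ratio of 0.991 (adjusted exact p = 0.822), and the M1BP site was lower in promoter peaks (3.14% against 4.75%, adjusted exact p = 0.000945), as were the initiator (17.1% against 31.1%, adjusted exact p = 6.76e-46) and the GAGA site (19.4% against 22.3%, adjusted exact p = 0.00448). Promoter summits had a median position 103 bp upstream of the TSS, so many 200 bp summit windows leave out the TSS, where the initiator lies. A lower share of sites near the TSS can therefore reflect window position, which was not separated from binding here. Flanks and the windows matched on GC content and class were not matched on distance to the TSS. The excess of promoter motifs over them, that of the Dref site included, can thus reflect position too. The M1BP site was 3.25 times as frequent as in matched controls, though lower than in promoters without a peak. Higher in promoter peaks than in promoters without a peak were TAATTA (18.6% against 9.84%, adjusted exact p = 3.37e-30), the su(Hw) core (7.96% against 4.28%, adjusted exact p = 5.68e-12), Ohler motif 7 (8.42% against 5.83%, adjusted exact p = 2.31e-05), GATA (35.7% against 31.4%, adjusted exact p = 0.000145) and the TCT initiator (19.2% against 16.0%, adjusted exact p = 0.000486). Those promoters were not matched on GC content. With the matched controls, over all peaks, TAATTA was not the only one of these to lose its call. The su(Hw) core (9.03% against 8.37%, adjusted exact McNemar p = 0.404), GATA (38.6% against 38.0%, adjusted exact p = 0.548) and the TCT initiator (20.3% against 21.8%, adjusted exact p = 0.170) did not pass the test either.

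With GC-matched control windows, chosen after seeing the data, the leading sequences were no longer made of A and T alone, and many held the core CACTG. ACAGTGG was in 6.14% of summit windows and 1.57% of controls (adjusted exact McNemar p = 9.47e-28), CAGTGTA in 6.14% and 1.86% (adjusted exact p = 1.47e-23), CACTGAG in 5.27% and 1.40% (adjusted exact p = 1.32e-22), and CTATCGA, which overlaps the Dref site, in 6.05% and 1.92% (adjusted exact p = 3.89e-21). The leading 6-mers were ACAGTG (15.5% against 6.38%, adjusted exact p = 8.57e-41) and ACACTG (16.1% against 7.01%, adjusted exact p = 2.19e-40). These controls were not matched on distance to the TSS.

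**Figure D4:**
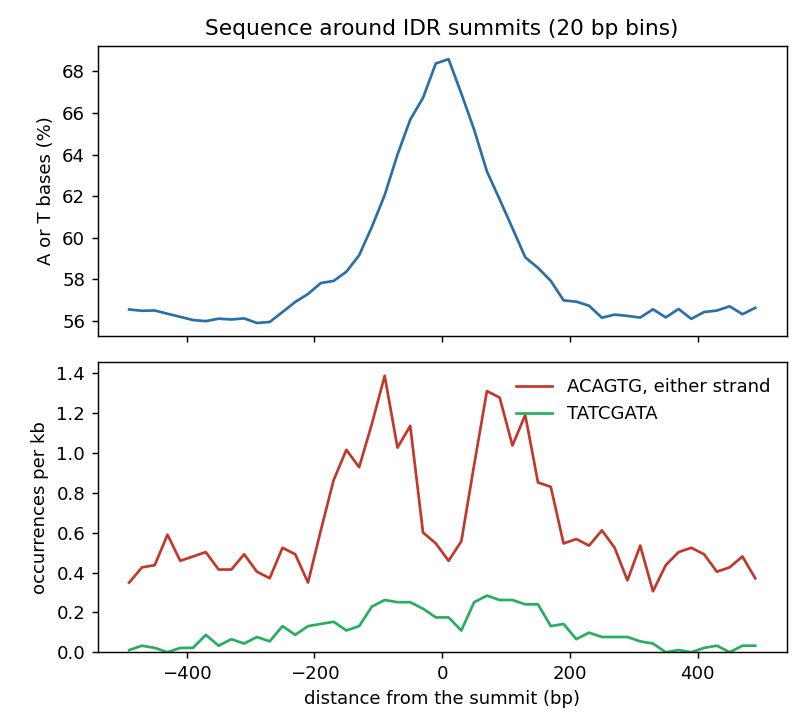
Percent of A or T bases (upper panel) and occurrences per kb of ACAGTG on either strand and of TATCGATA (lower panel) in 20 bp bins around 4576 IDR summits (x axis, bp). A and T bases peak at the summit (68.5% within 20 bp), and ACAGTG peaks on both sides of it, with 1.12 occurrences per kb from 60 to 160 bp and 0.541 within 40 bp.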

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

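Replicate 2 alone listed peaks on the mitochondrial genome, which entered no test and count only in the replicate 2 ranks printed here. It held 16 such peaks, all within its 29 strongest, with signals up to 9916, whereas replicate 3 and the pooled and IDR lists held 0. Whether mitochondrial reads were removed before some of the lists were called was not given in the sources used here, and no explanation was tested.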

How the results depend on the processing

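The promoter share, the excess at divergent promoters and replicate agreement kept their direction and their side of the threshold under every alternative run for them, and the number of classes that departed from their share stayed within 1.5 times. The number of arms, Y among them, that departed from their share went from 3 to 1 without Y in the total. The strongest 4576 pooled peaks are the IDR list itself, so that alternative changed nothing. The unknown depth limits what can be said of weak peaks. Controls matched on GC content and class, the restriction to peaks in both replicates, and arms without Y were chosen after seeing the data. The cause of the changes given here was not tested, and no paired analysis was possible because the design has a single group. The signal correlation was 0.687 with summits matched within 50 bp and 0.601 within 250 bp. The promoter minus distal difference ranged from 3.17 to 17.2 with a single replicate, each in its own list's signal (promoter to distal ratios of 1.03 and 1.13, against 1.09 in the IDR list), and was -4.18 with a TSS window of 200 bp. The number of gene lists past the threshold fell from 9 to 5 with summits outside repeats and to 2 with genes that had a pooled peak as background, and rose to 12 with replicate 3 alone (Notch, snRNA and ZAD-like lists gained) and to 11 with outermost TSSs (oxidative phosphorylation and ZAD-like lists gained). The number of motifs past the threshold went from 16 to between 10 and 18 with a single replicate, to 8 against promoters without a peak and to 8 with matched controls. The number of enriched k-mers went from 1150 to 457 for 6-mers, of which fewer exist, and to 275 with matched controls. The signal difference for AAAATAT was 14.4 in the stronger part of the list and no longer passed the test.

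Directions also turned for single classes, arms, lists and motifs, among them motifs that had passed the test (GAGA and GA repeats, CACGTG, CAGCTG, CA repeat, and the CTCF, BEAF-32, M1BP and Ohler 6 sites). The other exon share ranged from 0.743% to 0.852% with a single replicate, and was 1.55% with a TSS window of 200 bp and 0.481% with 1000 bp, and arm 2R had from 33.0 to 34.8 peaks per Mb with a single replicate and 25 with summits outside repeats, and arm 3R, with 33.6 peaks per Mb, changed sides of its share without Y. The Polycomb odds ratio was 1.30 in the stronger part of the list, 1.65 to 1.66 with a single replicate and 1.09 with a TSS window of 1000 bp. The odds ratio was 0.997 for oxidative phosphorylation in the stronger part, 1.22 for neural and 0.945 for cell cycle genes among peaks in both replicates, 0.644 for germline genes with 200 bp, and 1.21 for mesoderm regulators and 0.868 for C2H2 genes with the pooled background. Summit to flank ratios turned as follows. With a single replicate they ranged from 0.865 to 1.02 for GAGA, 0.611 to 1.17 for the long GAGA repeat, 0.664 to 1.08 for CACGTG, 0.969 to 1.05 for the initiator, 0.984 to 1.08 for the TCT initiator and 0.550 to 1.08 for the GA repeat. With 400 bp windows they were 1.09 for GAGA, 1.27 for its long repeat, 1.03 for CACGTG, 1.05 for CAGCTG, 1.09 for the CA repeat, 1.01 for the TCT initiator and 1.37 for the GA repeat. Against promoters without a peak they were 0.991 for the BEAF-32 core, 0.660 for M1BP, 0.894 for Ohler motif 6, 1.11 for the CA repeat and 1.20 for the TCT initiator. With matched controls they were 1.21 for GAGA, 1.24 for its long repeat, 1.13 for CACGTG, 1.61 for CAGCTG, 1.43 for the CTCF core, 1.11 for the CA repeat and 1.12 for the GA repeat. The initiator had 1.06 with summits outside repeats, and the TCT initiator 1.004 in the stronger part, 1.03 among peaks in both replicates and 1.02 with 100 bp windows.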

Other observations

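The tests in this part were chosen after the peaks had been seen, except that the expected outcomes of the GC-stratified, separate-arm, CG10147 neighbourhood and distal-peak tests were written before those values were computed. Among families of protein-coding genes grouped by the start of their symbol (67 families of at least 10 genes, Fisher's exact test, adjusted over the families), autophagy genes (Atg) had a promoter peak in 11 of 20 cases (odds ratio 4.80, adjusted exact p = 0.00483) and Rab GTPase genes in 13 of 31 (odds ratio 2.84, adjusted exact p = 0.0283). Families at the low end were cuticle proteins (Cpr, 0 of 70, adjusted exact p = 3.87e-06), cytochrome P450 genes (Cyp, 5 of 85, odds ratio 0.243, adjusted exact p = 0.00293), odorant-binding proteins (Obp, 2 of 51, adjusted exact p = 0.00956), pickpocket channels (ppk, 0 of 28, adjusted exact p = 0.0189) and Osiris genes (Osi, 0 of 25, adjusted exact p = 0.0266). Genes known only by a CG number had a promoter peak less often than named genes, 845 of 6097 (13.9%) against 1991 of 7848 (25.4%; odds ratio 0.473, 95% interval 0.433 to 0.517, exact p = 8.89e-65).

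Each of ACAGTG, ACACTG and CACTGAG had a preferred strand beside the summit, though the shared core did not have a single one, since ACAGTG carries CACTG on its other strand. From 50 to 150 bp away, ACAGTG read towards the summit in 738 of 1044 occurrences (70.7%, exact binomial p = 9.06e-42), ACACTG in 716 of 1024 (69.9%, exact p = 4.78e-38) and CACTGAG in 252 of 299 (84.3%, exact p = 4.65e-35). In matched control windows the shares were 50.7%, 53.8% and 56.2%. The ACAGTG share was 67.7% on arms 2L, 2R and 4 and 72.3% on 3L, 3R and X, and 68.3% and 73.3% around the strongest 4576 peaks of replicates 2 and 3. The words had been picked from all IDR peaks, with matched controls that were tried after flanks had given AT-rich words, so these splits are not independent tests. Peaks with ACAGTG had a median signal of 239.2 against 226.8 without it (adjusted permutation p = 0.0566), which did not pass the test.

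Technical readings of the sequence around summits were weighed. Avoidance of GC-rich coding exons was argued against by windows without a coding base, where the GC content at summits differed from that of other windows by -4.70 percentage points at promoters (95% interval -5.03 to -4.37) and by -6.72 in introns and intergenic sequence (95% interval -7.01 to -6.44). GC content as the sole reason for a call was argued against by the odds of a summit in promoter against intergenic windows, 10.7 within bins of GC content (95% interval 9.74 to 11.8). These odds were already 9.49 without bins, since promoter and intergenic windows differ little in GC content (42.6% and 40.7%), so binning had little to remove. GC content still went with calls: the share of promoter windows with a summit was 6.87% at 24 to 26% GC and 0.293% at 58 to 60% GC. A promoter layout that fixes the strand of the words was argued against by distal peaks, where 74.3% of ACAGTG occurrences read towards the summit (95% interval 70.4 to 77.9). A partial GC bias of the libraries stays open, since reads and the control were not analysed, and no biological explanation was tested.

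Promoter peaks may come in part from promoters that are recovered in any precipitation. The 6-mer found on arms 2L, 2R and 4 with matched controls was ACACTG, though such words had already been seen among the peaks of all arms. On 3L, 3R and X, 558 of 1934 genes with it near the TSS had a promoter peak (28.9%), against 1192 of 6422 without it (18.6%), with GC-stratified odds of 1.74 (95% interval 1.55 to 1.96). At a given GC content, promoter peaks on these arms were thus not independent of this word. Promoters recovered in any precipitation could share such words, so the odds cannot separate that recovery from binding. A contribution of such recovery stays open for all promoter peaks, those of ribosomal protein and glycolysis genes among them, since no other precipitation was analysed. No biological explanation was tested.

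The CG10147 promoter peak might reflect extra copies of the locus on the transgene. Within 10 kb of the gene the pooled list held 6 peaks, against a median of 8 and a 95th percentile of 16 around 1760 other genes with a promoter peak. These genes could be shorter or moderately longer than CG10147, and a longer gene gives a wider span to count in. The neighbourhood thus held no excess of peaks over those genes. This cannot decide whether the signal was raised across it, since peaks show raised reads only where they form a summit, and the list was called with a control that was not analysed. The span of the transgene was not given in the sources used here. Binding of CG10147 to its own promoter, or to that of Bulli, was not tested.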
